A study of Homo sapiens with 12 samples.

How the data were processed

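Libraries were made from poly(A)-selected RNA of H9 cells and of a DOT1L knockout derivative at successive days of differentiation to kidney organoids, with 1 library for each of 7 WT and 5 KO days. Genotype and day came from the sample titles, the unmodified stem cells being day 0. The submitters' processing notes name Bowtie2, RSEM and the hg38 genome build, without versions; read trimming, strand setting and gene annotation are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

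Each deposited file of a sample held RSEM's expected count, TPM and FPKM per gene for 33382 gene identifiers, per the file headers. The deposited expected count is an estimate that need not be whole, because reads that align to several genes are divided between them; it was rounded to whole numbers for the count tests. The deposited TPM is scaled by gene length and by library and was used for the rules on levels and as an alternative scale. The deposited FPKM values were not used. A deposited TPM table of the whole series held 33289 of the identifiers, 93 fewer, and its values differed from the files of the samples by at most 0. Of the identifiers, 32777 had a record in GENCODE release 29, which supplied gene types and GRCh38 coordinates. Symbols came from a separate list of current gene names, which covered 24406 identifiers, and otherwise from the deposited TPM table of the series. Of the 435 entries of 27 gene lists, 421 were matched. No identifier lay on the mitochondrial chromosome, so the mitochondrial list was empty and 26 lists were used. The 5 genes resembling ribosomal RNA held 0.1% (WT day 0) to 2.52% (KO day 16) of the expected count.

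The summed expected count was 2713358, 2003550, 2549630, 2118677, 2672890, 1435411 and 2626001 in WT days 0, 3, 6, 8, 9, 14 and 16 and 2348565, 2933625, 2479105, 1574030 and 2268998 in KO days 6, 8, 9, 16 and 19. Intervals are exact 95% intervals of the counts, and the floor of an undetected gene is 3 counts, per library unless a group is named; reads carry no molecular identifiers, so both cover counting error only. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom, over genes with at least 20 counts in the pair, was 6.08, between WT days 6 and 8.

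Counts were normalised by the trimmed mean of M values and tested in edgeR 4.0.16 (quasi-likelihood F test) under R 4.3.3, on the 8 libraries of the 4 matched days with genotype and day as terms, after edgeR's expression filter with a count minimum of 10, which left 12869 genes. The day 9 against 6 and day 16 against 9 comparisons came from the same fit, in which each day had 1 library per genotype, and the KO-by-day-16 interaction from a fit with that term added. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05; the count "adjusted over the list alone" repeats this within a list. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with an estimated correlation and with fry as alternatives. KO and WT values are normalized CPM with the SD over the 4 days, which includes the change between days.

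Comparisons with 1 library a side were described and not tested: ratios of normalized CPM with exact counting intervals, log2 ratios with 0.5 CPM added, and list medians placed among 10000 random lists of the same size matched on mean expression. For likeness between libraries, log2 CPM was centred over the WT libraries and compared across the 1000 most variable genes. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

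The genes named were chosen by a rule fixed before the data were examined, as were the lists, the tests and the alternatives not called added. For the KO comparison it took DOT1L, then the 10 largest rises and the 10 largest falls with adjusted p under 0.05, the same sign on all 4 days and a mean of at least 5 CPM in the higher genotype, leaving out unnamed genes, pseudogenes and antisense genes, and up to 4 members per list by adjusted p. The day comparisons took 5 rises and 5 falls by the same rule and up to 4 members per list, the interaction the 5 smallest adjusted p, the WT course up to 3 members per list by highest TPM and the 3 largest rises and falls of each step at 20 TPM or more, and KO day 19 the 5 largest of each. Some list members outside this rule, namely SIX2, SIX1, OSR1, EYA1, HNF1B and CUBN, were named after their values were seen.

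The tests were tried on simulated counts drawn from the means and library sizes of the matched libraries, with 200 genes changed by known amounts. For the KO comparison the filter left 12371 of the simulated genes, and the shares here and below count only changed genes that it left. There edgeR recovered 4.1%, 73.9%, 98% and 100% of the 49, 46, 50 and 46 genes changed by 1, 2, 3 and 5 on the log2 scale. It made 6 false calls among 137. For the interaction, with 12352 genes, it recovered 69.4% of changes of 5 and made 10 false calls among 57. For day 9 against 6 and day 16 against 9 it recovered 89.4% and 97.9% of changes of 5. In those simulations every day difference was removed before the change was added, a simpler setting than the data. The shares therefore do not give the sensitivity in the data, where NOTUM, at log2 6.90 for day 9 against 6, did not pass.

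The alternatives were DESeq2's size factors and upper-quartile normalization, no filter or 1 CPM in 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom, limma-trend on log2(TPM + 1) for genes at 1 TPM in 2 libraries, protein-coding genes alone, no day term, and each matched day left out. For the unreplicated comparisons they were deposited TPM in place of CPM and 2 CPM added before the log, and for likeness 3000 genes, all genes, and Pearson correlation. Added after seeing the data were likeness without centring, genes with whole counts in all 8 libraries, libraries thinned to the shallowest, removal of the ribosomal-like genes, and library offsets fitted against the GC content of each gene's longest transcript. The expected counts mix cell types within an organoid, so a level reflects both expression and cell composition.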

Results

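Poly(A)-selected RNA was sequenced from H9, an established human embryonic stem cell line, during directed differentiation through primitive streak, nephrogenic intermediate mesoderm and nephron progenitors to kidney organoids. The unmodified line (WT) was sampled at days 0, 3, 6, 8, 9, 14 and 16, and a derivative carrying a knockout of DOT1L, the methyltransferase of histone H3 lysine 79, at days 6, 8, 9, 16 and 19 (KO). Each genotype and day had 1 library, 12 libraries in all. The summed expected count per library ran from 1435411 in WT day 14 to 2933625 in KO day 8. The floor for an undetected gene, 3 counts, corresponded to 1.04 to 1.99 CPM, the count scaled to the normalized library total. The 4 days sampled in both genotypes gave the only replication of the KO difference, and nothing in the labels says that the libraries came from separate cultures, so p-values measured the spread between these libraries only.

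DOT1L itself, on chromosome 19 from 2164149 to 2232578 (GRCh38 coordinates of the GENCODE release 29 annotation, here and for all genes below), was lower in every KO library than in any WT library. Its level in WT was 248.8 CPM at day 0, 180.5 at day 3, 443.3 at day 6, 387.1 at day 8, 479.4 at day 9, 301.6 at day 14 and 303.7 at day 16. In KO it was 106.4 CPM at day 6, 68.8 at day 8, 111.5 at day 9, 102.9 at day 16 and 36.4 at day 19. Over the matched days DOT1L fell by 2.05 on the log2 scale (SE 0.257, edgeR quasi-likelihood test, adjusted p = 0.00998). Its mean went from 403.4 ± 76.5 CPM in WT to 97.4 ± 19.4 in KO (SD, n = 4 days). Reads were therefore still assigned to DOT1L in KO. DOT1L had non-whole counts in 6 of the 8 matched libraries, so part of its level may be reads shared with other genes. Its adjusted p was 0.061 without day 6, 0.0647 without day 8 and 0.0616 without day 9. The position of the edit within the gene is not given in the sources used here.

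**Figure D1:**
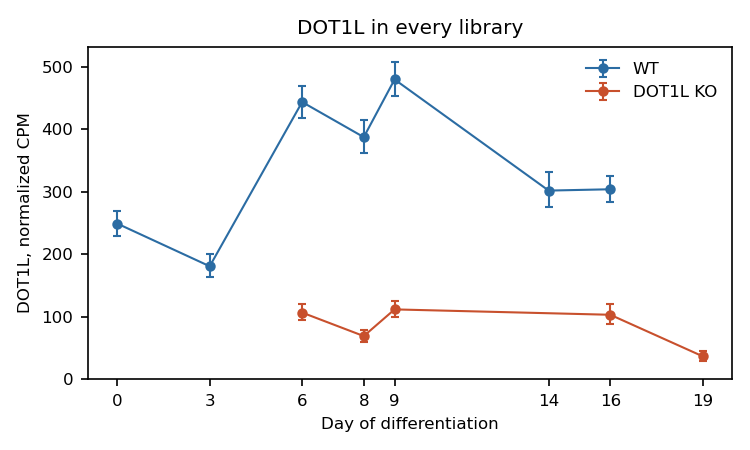
Normalized DOT1L level in CPM (y axis) by day of differentiation (x axis) in the 7 WT and 5 KO libraries; each point is 1 library and the bars are 95% exact Poisson intervals, which cover counting error only. The highest KO level, 111.5 CPM at day 9, lies under the lowest WT level, 180.5 CPM at day 3.

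The WT series asked how expression changed from stem cell to organoid. From day 0 to day 3 the genes of the primitive streak appeared: TBXT, the brachyury gene of nascent mesoderm, went from 0 counts to 652.5 CPM, at least 550.8-fold over the floor of the day 0 library. MIXL1, another streak gene, went from 1.57 to 1318 CPM and the WNT antagonist DKK1 from 0 counts to 689.8 CPM (at least 582.4-fold). The pluripotency gene POU5F1 was at 1469 CPM at day 0, 562 at day 3 and 2.3 at day 6, and DNMT3B, a DNA methyltransferase of pluripotent cells, at 2374, 396.8 and 151.5 CPM. MSX1, a BMP-responsive homeobox gene, was at least 327.8-fold higher at day 3, while IDO1 was at least 16.5-fold lower. NPTX1 and MEGF10 were at 0.0189 and 0.0118 of their day 0 levels (counting intervals 0.00611 to 0.0447 and 0.000295 to 0.0671). The medians of the fixed lists of canonical WNT targets and of primitive streak genes were higher by 6.84 and 5.38 on the log2 scale, and that of pluripotency genes was lower (log2 -2.55). These medians lay at or beyond 100, 100 and 0 percent of random lists matched on expression.

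Between day 3 and day 6 the intermediate mesoderm programme came up with the HOX genes, the regulators of position along the body axis. PAX8, a transcription factor of the kidney lineage, was at 0.479 CPM at day 3 and 392.6 at day 6, its partner PAX2 at 2.39 and 60.6, and WT1, later a podocyte regulator, at 0.479 and 102 CPM. HOXA9 and HOXD3 went from 0 counts to 332.8 and 214 CPM (at least 231.8-fold and 149-fold), HOXB9 from 51.2 to 1419 CPM, and the nuclear receptor gene NR2F1 from 0 counts to 393.4 CPM (at least 273.9-fold). MIXL1 was at 3.07 CPM at day 6, 0.00233 of its day 3 level (0.001 to 0.00459). The WNT target DKK4 was at least 133.6-fold lower and NKX1-2 was at 0.00242 of its earlier level (0.000292 to 0.00876). The list medians were higher by 5.09 for nephron progenitors, 4.14 for intermediate mesoderm, 4.06 for the HOX clusters, 2.92 for renal stroma, 2.72 for chondrogenic genes and 2.05 for imprinted genes. Among the imprinted genes IGF2 was at 12.4 and 5092 CPM.

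Few genes separated days 6 and 8. LUM, a collagen-binding proteoglycan, was 31-fold higher at day 8 (11.8 to 116) and NRK was 7.72-fold higher (5.74 to 10.6). LEFTY2, a NODAL antagonist, and FMOD were at 0.122 (0.0953 to 0.153) and 0.118 (0.0614 to 0.21) of their day 6 levels. EIF3CL and HIST2H2AA3, which also headed this step, have near-identical copies that share their reads, and their values are uncertain. In this step 224 genes with at least 20 TPM on the higher side differed 2-fold or more, or 358 in the deposited TPM. The same count was 1259 from day 0 to 3, 2025 from day 3 to 6, 1236 from day 8 to 9, 1310 from day 9 to 14 and 947 from day 14 to 16.

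At day 9 the WNT targets and the hypoxia and glycolysis genes were up together relative to day 8. NOTUM, a secreted WNT deacylase, was at 15.6 CPM at day 8 and 339.8 at day 9 (21.8-fold, 15.5 to 31.8), and SP5 at 11 and 216.8. BHLHE40, a hypoxia-inducible repressor, was 55.7-fold higher (23.6 to 172.8) and STC1 25.6-fold (14.1 to 51.7). ENO1 and LDHA, glycolytic enzymes, were at 1085 and 360.6 CPM at day 8 and 4670 and 1708 at day 9. The medians of the hypoxia list and the WNT target list were higher by 2.09 and 0.93. EBF2 was at 0.0336 (0.0121 to 0.0748) and CNTNAP4 at 0.0415 (0.0239 to 0.0674) of their day 8 levels. CXCR4 was at 15.6 and 290.4 CPM, and the median of the stromal list was lower (log2 -0.99).

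From day 9 to day 16 genes of differentiated nephron segments appeared. NPHS1, the gene of nephrin in the podocyte slit diaphragm, was at 0 counts at day 9, 185.2 CPM at day 14 and 1740 at day 16. NPHS2, which encodes podocin, was at 0, 31.8 and 1051 CPM and PODXL at 52.7, 149.5 and 1653 CPM. CLDN5, a tight junction gene of endothelium that podocytes also express, went from 0 counts to 213.7 CPM at day 14 (at least 177.1-fold) while CDH5, the endothelial cadherin, reached 24.2 CPM at day 16. POU3F3, a regulator of the distal nephron, was at least 99.2-fold higher at day 14, and HNF1B was at 2.01, 64.8 and 232.1 CPM. LRP2 and CUBN, the megalin and cubilin receptors of the proximal tubule, were at 155.1 and 69.3 CPM at day 16 against 6.03 and 0.804 at day 9. The podocyte median was higher by 2.42 at day 14 and by a further 2.5 at day 16. The median of the renal vesicle list was higher by 2.5 and that of the Notch list by 2.05 from day 9 to 14. The proximal tubule median was higher by 2.11 from day 14 to 16, where MT1G, HGD and MAOB were at least 16.7-fold, 13.6-fold and 13.4-fold higher. GREM1 and SP5 were at 0.00713 (0.00231 to 0.0167) and 0.00916 (0.00188 to 0.0269) of their day 9 levels at day 14, and GATA5 at 0.0693 (0.0214 to 0.175) of its day 14 level at day 16. BLOC1S5-TXNDC5, EIF3CL and HIST2H2AA4, also among the largest falls of level, are a readthrough locus and genes with near-identical copies, and their values are uncertain. Each WT day had 1 library, so none of these differences had a replicate check, and the intervals given are counting intervals.

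**Figure D2:**
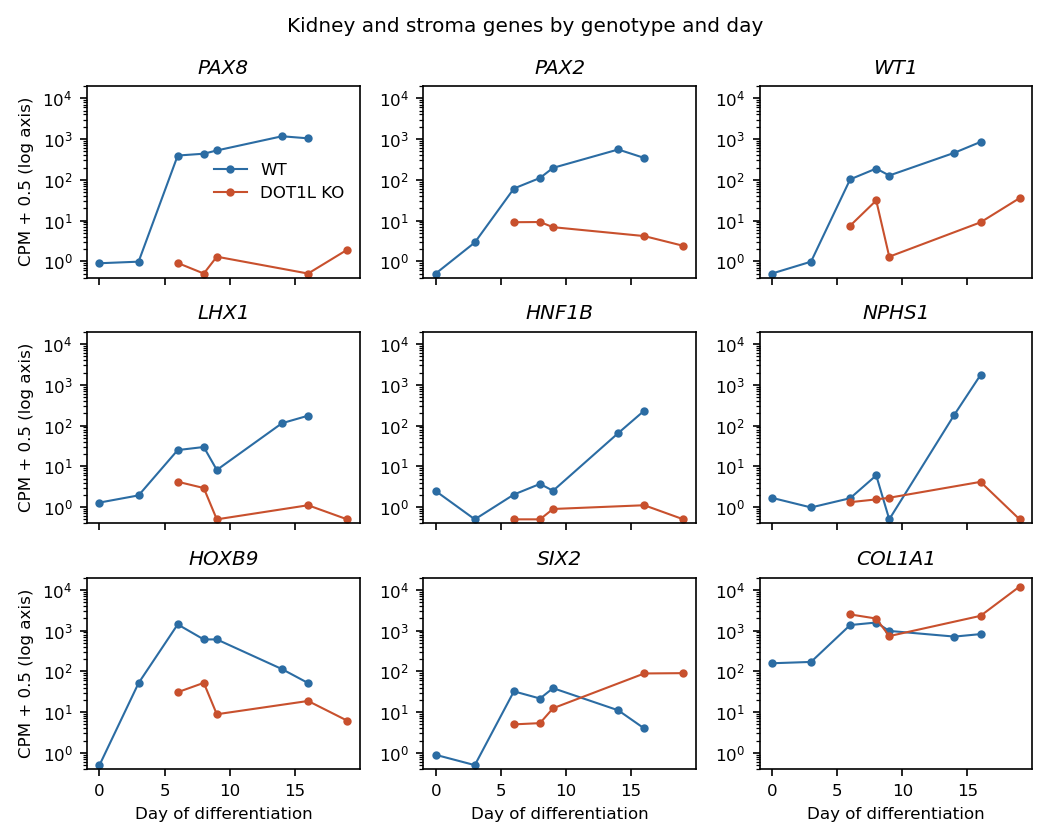
Level of 9 genes (y axis, CPM plus 0.5 on a log axis) by day of differentiation (x axis) in WT and KO; each point is 1 library. PAX8 stood at 392.6 CPM or more in WT from day 6 on and at 1.42 CPM or less in KO, and COL1A1 reached 12050 CPM in KO day 19.

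The KO comparison asked which genes differed between the genotypes on average over the 4 matched days, so a called gene need not differ on every day. Several transcription factors of the nephron lineage were lower in KO. PAX8 fell by 10.53 on the log2 scale (SE 0.558, adjusted p = 0.000188), from 597.7 ± 299.4 CPM in WT to 0.301 ± 0.382 in KO (SD, n = 4). It had 3 counts in the 4 KO libraries together. WT1 fell by 4.73 (SE 0.725, adjusted p = 0.0211), and PAX2 by 4.35 (SE 0.554, 0.0107). LHX1, needed for the renal vesicle, fell by 4.43 (SE 0.752, 0.0286) and SALL1, a regulator of nephron progenitors, by 2.72 (SE 0.366, 0.0122). Others of these lists did not pass, among them SIX2, SIX1, OSR1 and EYA1 (adjusted p = 0.679, 0.284, 0.43 and 0.35). On the other side the matrix genes POSTN and COL3A1 rose by 3.06 (SE 0.446, 0.0173) and 2.20 (SE 0.374, 0.0286). COL3A1 was at 1300, 2950, 1551 and 3907 CPM in KO days 6, 8, 9 and 16 and 349.7, 939.9, 488.6 and 310.3 in WT. In all, 222 of 12869 genes tested passed an adjusted p of 0.05 in edgeR, 99 higher and 123 lower in KO. The count was 63, 46 and 50 without day 6, 8 and 9 and 695 without day 16, and 774 by DESeq2.

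The 10 largest falls among genes moving the same way at all 4 days were led by PAX8 (chromosome 2, 113215997 to 113278950). SALL3, a zinc finger gene of the SALL family, had a log2 difference of -8.06 (SE 0.672; chromosome 18, 78980275 to 79002677). That of DACH2 was -7.01 (SE 0.659; chromosome X, 86148458 to 86832604), and that of FGF8, a growth factor of the renal vesicle, -6.28 (SE 0.989; chromosome 10, 101770130 to 101780369). CLEC18C followed at -5.85 (SE 1.14; chromosome 16, 70173322 to 70187361) and the glucagon receptor gene GCGR at -4.84 (SE 0.768; chromosome 17, 81804132 to 81814013). SHISA8 was at -4.84 (SE 0.978; chromosome 22, 41909554 to 41914667) and CTNNA2, a neuronal alpha-catenin, at -4.83 (SE 0.566; chromosome 2, 79185231 to 80648861). WT1 lies on chromosome 11 from 32387775 to 32435630. SPOCK2 closed the group at -4.71 (SE 0.467; chromosome 10, 72059035 to 72089032). Their adjusted p ran from 0.000188 for PAX8 to 0.0476 for SHISA8. SALL3 was at 43.7 ± 11.7 CPM in WT and at 1 count over the 4 KO libraries. CLEC18C has close paralogs, had non-whole counts in 5 of the 8 libraries and stood at 465 CPM in WT day 16 against 4.6, 12.3 and 4.83 on the earlier days, so its value is uncertain.

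The 10 largest rises included CAT, the gene of catalase (log2 7.83, SE 0.674; chromosome 11, 34438925 to 34472062). It had 1 count over the 4 WT libraries and stood at 33.7 ± 6.27 CPM in KO. MEG3, a maternally expressed long noncoding RNA of the imprinted DLK1 locus, rose by 7.79 (SE 1.1; chromosome 14, 100779410 to 100861031). MEG3 was at 80.2, 494.5, 97.53 and 1034 CPM in KO days 6, 8, 9 and 16 against at most 4.6 in WT. HOXD13, the last gene of the HOXD cluster (6.71, SE 0.82; chromosome 2, 176092891 to 176095938), and TBX4, a hindlimb regulator (5.57, SE 0.525; chromosome 17, 61452404 to 61485110), were among them. The growth factor gene IGF1 was another (5.13, SE 0.968; chromosome 12, 102395874 to 102481744). So were LRRC61 (6.12, SE 0.844; chromosome 7, 150322639 to 150338150) and the cathepsin gene CTSF (5.81, SE 0.775; chromosome 11, 66563463 to 66568841). The others were the carboxylesterase gene CES1 (5.74, SE 0.75; chromosome 16, 55802851 to 55833337), C9orf64 (chromosome 9, 83938311 to 83956986) and the readthrough locus MSANTD3-TMEFF1 (chromosome 9, 100442271 to 100577636). C9orf64 and MSANTD3-TMEFF1 had no count in the 4 WT libraries and were at least 37.3-fold and 47.3-fold higher in KO, against a floor of 3 counts over the group. Reads of MSANTD3-TMEFF1 are shared with the genes it spans. IGF1 had non-whole counts in 6 of the 8 libraries, so part of its level may also be shared reads. The adjusted p of these rises lay between 0.00255 for CAT and 0.0389 for IGF1.

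Genes high in GC content were lower in KO as a class. Tested genes were divided into 5 classes of equal size by the GC content of the longest transcript. The median log2 difference was 0.41, 0.21, -0.01, -0.27 and -0.49 from the lowest to the highest class, with KO day 8 as the exception among KO libraries. The share of 7913 well-counted genes with a non-whole expected count was 25.2% to 29.9% in KO and 18.5% to 21.7% in WT. The mean fragment or read length implied by the deposited effective lengths was 85.6 to 93.7 bases in KO and 99.4 to 103.6 in WT on the matched days. Over the whole series the genotypes overlapped: it was 89.2 and 93.4 in WT days 0 and 3, 100.2 in WT day 14 and 91.6 in KO day 19. The labels name no batch, and differences of culture or processing that follow genotype were neither tested nor excluded. With library offsets fitted against GC content, an alternative added after seeing the data, 128 genes passed (70 higher and 58 lower; 114 shared with the 222). DOT1L was at log2 -1.58 (adjusted p = 0.0459), and of the 20 genes named above 17 passed and 3 lost the call: CLEC18C was at log2 -5.51 (adjusted p = 0.0656), SHISA8 at -4.14 (0.109) and IGF1 at 4.69 (0.0554).

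**Figure D3:**
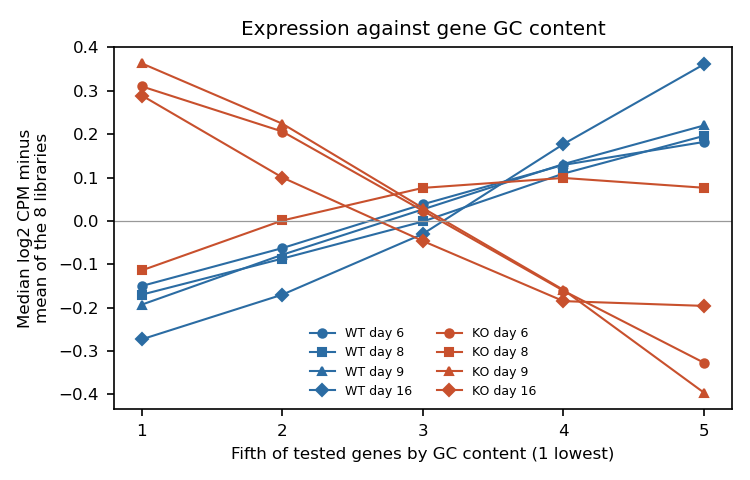
Median difference of each matched library's log2 CPM from the mean of the 8 libraries (y axis) in 5 equal classes of the tested genes by GC content (x axis, 1 lowest); each line is 1 library. In the highest class the 4 WT libraries lay between 0.18 and 0.36 and the KO libraries of days 6, 9 and 16 between -0.40 and -0.20, with KO day 8 at 0.08.

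By fixed list, the early kidney groups were lower. These lists share members, so their results are not independent. PAX2 and WT1 belong to both the intermediate mesoderm and nephron progenitor lists, and PAX8 and LHX1 to both the intermediate mesoderm and renal vesicle lists. Of 10 intermediate mesoderm genes tested, 4 fell, PAX8, PAX2, WT1 and LHX1, and HOXD11 rose (5 and 2 adjusted over the list alone). The list was lower by camera at adjusted p = 0.00114, and at 0.315 with an estimated correlation. Of 14 nephron progenitor genes, 4 fell, among them PAX2, WT1 and SALL1, and HOXD10 rose by 1.96 (6 and 1 adjusted over the list alone). The camera adjusted p of that list was 0.000187, and 0.316 with an estimated correlation. Of 12 renal vesicle genes 5 fell, with PAX8, FGF8, LHX1 and SFRP2 (log2 -1.41) having the smallest adjusted p, and 7 did adjusted over the list alone (camera adjusted p = 4.11e-08, and 0.267 with an estimated correlation). Over tested genes the median of the nephron progenitor list was below 0 at days 6, 8 and 9 (log2 -2.85, -2.51 and -1.89) and above 0 at day 16 (0.51). At day 16 SIX2, which marks self-renewing nephron progenitors, stood at 88.3 CPM in KO and 3.46 in WT. The renal vesicle median over tested genes was -2.55 at day 16, and -3.06 over all 15 members. With offsets against GC content the same 3 lists were at adjusted p = 0.000819, 0.000215 and 5.78e-09, with 4, 3 and 3 genes falling, and non-whole counts were more frequent in KO throughout.

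The HOX clusters went both ways. Of 32 HOX genes tested, 13 fell and 3 rose (25 and 5 adjusted over the list alone). With GC offsets 5 fell and 3 rose. HOXB6 fell by 4.10 (SE 0.547, adjusted p = 0.0119), HOXB8 by 3.14 (SE 0.346, 0.00666) and HOXD4 by 2.45 (SE 0.354, 0.0167). HOXD13, HOXD11 (log2 2.10, SE 0.34, 0.0252) and HOXD10 rose. HOXD10 was at 62.6, 45.9, 62.5 and 17.1 CPM in KO and 13, 21.1, 11.3 and 4.23 in WT, on days 6, 8, 9 and 16. The list was lower by camera (adjusted p = 2.66e-10, and 0.315 with an estimated correlation). Genes of the HOXD cluster lie close together and overlap, so reads between them can be shared.

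The stromal list of 14 tested genes was higher (camera adjusted p = 0.000203, and 0.316 with an estimated correlation; 1.75e-05 with GC offsets). Of its genes 2 rose, POSTN and COL3A1, 4 did adjusted over the list alone, and none fell. DCN and LUM did not pass (adjusted p = 0.0849 and 0.131): on days 6, 8, 9 and 16 LUM was at 29.9, 49.7, 76 and 51.8 CPM in KO and 1.53, 47.6, 15.3 and 1.16 in WT. The median of the list over tested genes was 0.80, 0.39, 0.61 and 2.72 on these days. Of 13 hypoxia and glycolysis genes, 4 fell, and 9 did adjusted over the list alone. The 4 were the hexokinase gene HK2 by 1.96 (SE 0.253), the glucose transporter gene SLC2A1 by 2.51 (SE 0.464), BNIP3 by 1.74 (SE 0.323) and VEGFA by 1.60 (SE 0.265). The list was lower by camera (adjusted p = 4.18e-07, and 0.315 with an estimated correlation). With GC offsets SLC2A1 and BNIP3 were at log2 -2.27 and -1.62, close to their size without them, and at adjusted p = 0.052 and 0.0505. NOTCH1 fell by 1.40 (SE 0.255), the only one of 14 Notch genes to pass, with 6 lower adjusted over the list alone (camera adjusted p = 0.000254, and 0.315 with an estimated correlation). With GC offsets NOTCH1 was at log2 -0.92 (adjusted p = 0.17).

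Smaller lists were also lower by camera: podocyte (adjusted p = 0.0132, and 0.4 with an estimated correlation), primitive streak (0.0132 and 0.315), pluripotency (0.021 and 0.316) and imprinted genes (0.0447 and 0.464). VEGFA alone of 8 podocyte genes passed, with 4 lower and 1 higher adjusted over the list alone, and the call was lost without day 16 (adjusted p = 0.268). FGF8 was the 1 primitive streak gene of 4 to fall, none of 6 pluripotency genes did in edgeR (3 adjusted over the list alone), and MEG3 rose in an imprinted list whose median was negative (log2 -0.57). Pluripotency was at adjusted p = 0.0554, 0.21 and 0.0815 without day 6, 8 and 9, primitive streak at 0.0554 without day 6, and imprinted genes at 0.154 without day 6 and 0.156 without day 8. No list passed with an estimated correlation and 4 passed by the self-contained fry test, namely HOX clusters, primitive streak, intermediate mesoderm and renal vesicle. These 4 overlap: FGF8 is also a renal vesicle gene, HOXD11 an intermediate mesoderm gene, and PAX8 and LHX1 are in both kidney lists. VEGFA is also in the hypoxia list.

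The remaining 15 lists were not called. KDR, a VEGF receptor gene, fell by 3.65 (SE 0.524, adjusted p = 0.0164) among 3 endothelial genes tested, and CDH6 by 4.37 (SE 0.542, 0.00944) among 7 proximal tubule genes. KRT19 fell by 2.71 (SE 0.437, 0.0251) among 7 ureteric and collecting duct genes, and IRX2 by 2.10 (SE 0.424, 0.0476) among 5 distal genes. EGR1 fell by 2.18 (SE 0.426, 0.0449) among the FGF and ERK and the stress lists of 13 and 12. With GC offsets IRX2 was at log2 -1.73 (adjusted p = 0.115), EGR1 at -1.92 (0.0644) and the renal vesicle gene SFRP2 at -1.29 (0.0644). No gene passed in edgeR among 20 cell cycle, 16 DOT1L complex, 14 p53, 13 BMP and TGF-beta, 11 canonical WNT, 10 chondrogenic, 6 muscle, 4 neural or 3 endoderm genes. Their camera adjusted p were 0.209, 0.836, 0.281, 0.691, 0.0827, 0.221, 0.838, 0.936 and 0.108, and those of the proximal tubule, distal, ureteric, endothelial, FGF and stress lists 0.0633, 0.736, 0.836, 0.836, 0.726 and 0.836. Without day 9 the WNT and proximal tubule lists passed by camera (adjusted p = 0.0182 and 0.0453). Without day 16 the WNT, endoderm and FGF lists did (0.0185, 0.0185 and 0.0403). No other of these lists passed with a day left out. The DOT1L partner MLLT1 was at 162.5, 172, 199 and 123.6 CPM in KO and 169.9, 160.6, 147.2 and 217.1 in WT on the matched days. The mitochondrial list had no counterpart among the gene identifiers.

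**Figure D4:**
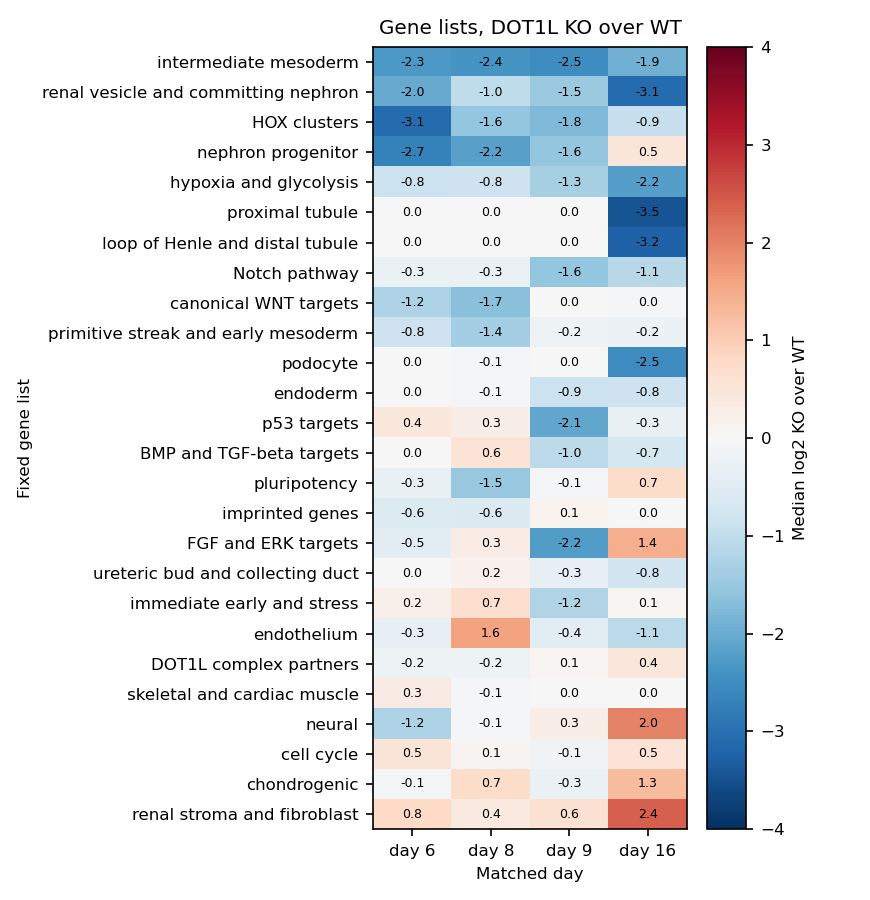
Median log2 ratio of KO over WT (colour and printed value) over all members of each of 26 fixed gene lists (y axis) at each of the 4 matched days (x axis); each cell compares 1 library per genotype. Intermediate mesoderm ran from -1.91 to -2.49, and proximal tubule stood at -3.46 and renal stroma at 2.4 at day 16.

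At day 16 alone the genotypes differed in segment genes, among others, many of which were too low on the other days to enter the test. The KO day 16 library also had the highest share of genes resembling ribosomal RNA, 2.52% against 0.531% in WT day 16. The stress list had a median of log2 1.16 over tested genes at day 16. On days 6, 8 and 9 it was 0.21, 0.66 and -1.14. ASNS and DDIT3 were at 369.7 and 81.6 CPM in KO day 16 and 21.9 and 10.4 in WT. HSPA1A, with non-whole counts in all 8 libraries, was at 1398 and 261 CPM. FOS and EGR1 of the same list were lower in KO. Whether these traits bear on the other day 16 differences was not tested. NPHS1 was at 1740 CPM in WT and 3.65 in KO (0.0021 of the WT level, counting interval 0.00077 to 0.00457). NPHS2 was at 1051 CPM in WT and 0 counts in KO (at least 575.3-fold lower) and HNF1B at 232.1 and 0.609 CPM. LRP2 was at 155.1 and 3.04, CUBN at 69.3 and 3.04 and EPCAM, an epithelial adhesion gene, at 100.1 and 4.87 CPM. COL1A1 was at 2301 CPM in KO and 819.9 in WT (2.81-fold, 2.66 to 2.96), and DCX, a gene of migrating neurons, at 310.6 and 9.62. With 1 library a side these values compare those libraries, not the conditions. In them 3799 genes with at least 20 TPM on the higher side differed 2-fold or more, against 1514, 1198 and 1630 at days 6, 8 and 9.

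Between day 9 and day 6 in both genotypes, the NODAL antagonist LEFTY2 fell by 7.22 on the log2 scale (SE 0.713, edgeR adjusted p = 0.0406; chromosome 1, 225936598 to 225941489). It went from 297.2 and 751.9 CPM in WT and KO day 6 to 2.01 and 4.78 at day 9. It was the 1 gene called in this comparison, with 438 at an unadjusted p under 0.05, 65 by DESeq2, 2 by limma-voom, 0 without day 8 and 34 without day 16. The WNT targets NOTUM, SP5 and NKD1 had log2 differences of 6.90, 5.57 and 3.93 (adjusted p = 0.128, 0.169 and 0.544), and 8 of 11 WNT genes and 6 of 13 hypoxia genes passed adjusted over the list alone. VEGFA and HK2 had log2 differences of 2.54 and 2.35 (both at adjusted p = 0.172).

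From day 9 to day 16 no gene passed in edgeR, with 1886 at an unadjusted p under 0.05, 518 called by DESeq2, 1 by limma-voom and 2 on log2 TPM. The smallest adjusted p among listed genes were those of NOTUM and SP5 (log2 -6.87 and -7.29, both 0.064), JUN (2.55, 0.0662), the YAP and TGF-beta target CCN2 (7.23, 0.0736) and LIN28A (-5.95, 0.0835). MAFB, a podocyte transcription factor, was at 2.81 and 1594 CPM in WT and 3.18 and 31.1 in KO. Adjusted over the list alone, 7 of 8 podocyte genes, 12 of 20 cell cycle genes, 7 of 11 WNT genes and 5 of 12 renal vesicle genes passed. MCM2, a replication licensing factor, was at 403 and 144.7 CPM in WT and 263.9 and 35.9 in KO on days 9 and 16.

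The test of whether the KO difference at day 16 departed from that at days 6, 8 and 9 called 308 genes in edgeR, 181 with a more positive and 127 with a more negative difference at day 16. THSD4, an extracellular matrix gene, was at 618.2 CPM in KO day 16 and 9.24 in WT, but at 27.4, 13.6 and 38.2 in KO and 23.8, 16.9 and 63.5 in WT on the earlier days. SYNPO, the podocyte actin-binding gene synaptopodin, was higher in KO on days 6, 8 and 9 (115.8, 91.1 and 43.4 CPM against 4.22, 4.58 and 4.02) and lower at day 16 (150.4 against 564.7). The transcription factor gene EBF2 was at 234.5 CPM in KO day 16 and 1.92 in WT, RIMS4 at 74.3 and 1.54, and IL1R1 at 6.09 and 484.7. All 5 had an adjusted p of 0.00501, the smallest in the comparison. The count was 668 without day 8, 1627 without day 9, 501 by DESeq2 and 0 on log2 TPM, and day 16 had 1 library a side. The spread in this test came from days 6, 8 and 9 alone, so a peculiarity of a day 16 library is not separated from a change in the KO difference.

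KO day 19 had no WT partner and was set beside KO day 16. The largest rises at day 19 included ASPN and SPARCL1, which went from 0 counts to 65.3 and 63.9 CPM (at least 35.7-fold and 35-fold). PRSS35 was 92.7-fold higher (55.1 to 169.9). Matrix genes as a class were not tested. COL1A1, COL1A2 and COL3A1 stood at 12050, 11520 and 12470 CPM against 2301, 3694 and 3907. PALM2AKAP2 and CYP4X1 were at least 31.3-fold and 26.7-fold higher, PALM2AKAP2 being a fused locus of uncertain read assignment. GDF15 and CXCL1 were at least 53.6-fold and 27.5-fold lower, and ICAM1 was at 0.021 of its day 16 level (0.0124 to 0.0335). GDF15 stood at 76.1 CPM in KO day 16, against 5.73, 6.6 and 0.398 in KO days 6, 8 and 9. ELF3 was at 0.0109 (0.000273 to 0.0629) and GAP43, a neuronal growth gene, at 0.0132 (0.000328 to 0.0763). PAX8 was at 1.42 CPM, NPHS1 at 0 counts, which allows up to 1.42 CPM, and WT1 at 35 CPM. The stromal and chondrogenic medians were higher by 1.19 and 1.31 and the hypoxia median lower (log2 -1.50), each outside all 10000 random lists, and no replicate check was possible.

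The likeness of each KO library to the WT days was measured as a Spearman correlation across the 1000 genes most variable in WT, which are not independent replicates. KO day 16 and day 19, in which the podocyte gene NPHS2 was at 0 counts, lay closest to WT day 8 (rho 0.244 and 0.3), and KO day 16 had rho 0.0278 with its own day. Without centring over the WT libraries, an alternative added after seeing the data, KO day 16 had rho 0.362 with its own day and 0.61 with WT day 8, still the closest. KO day 6 lay closest to WT day 8 (0.418, against 0.407 with day 6), KO day 8 to day 8 (0.513) and KO day 9, in which NOTUM and SP5 were up as in WT day 9, to day 9 (0.369). KO day 16 and KO day 19 had rho 0.703 with each other. With KO days 6, 8 and 9, KO day 16 had rho 0.519, 0.556 and 0.49, higher than with any WT day. Without centring these were 0.739, 0.749 and 0.703. Its rho with WT days 6 and 9, 0.192 and 0.2, was near the 0.244 with WT day 8, so the closest day was set apart by little.

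**Figure D5:**
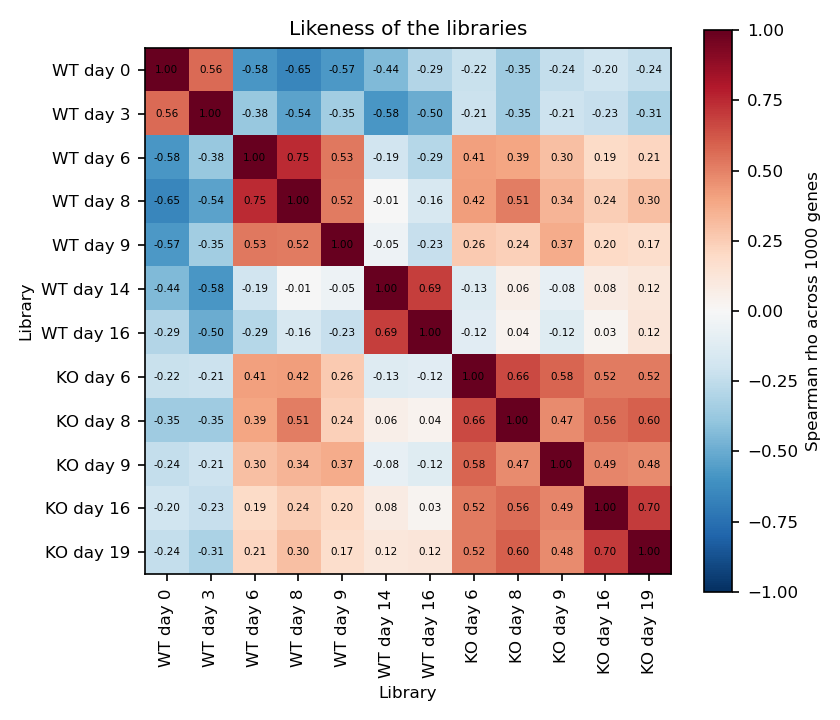
Spearman correlation (colour and printed value) between each pair of the 12 libraries over the 1000 genes most variable among WT days, on log2 CPM centred over WT; both axes list the libraries. KO day 16 correlates at 0.24 with WT day 8 and at 0.03 with WT day 16.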

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

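The tests of cell composition, of other splits by gene count, of ambiguous reads and of a whole autosome were chosen after the results they measure were seen, as were the test of GC content, prompted by the medians per chromosome, and the limits that define genes near the floor.

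SYNPO and EBF2 were among the 5 genes with the smallest adjusted p for a departure of day 16 from the earlier days. The KO-by-day-16 term of edgeR was 6.399 on the log2 scale for THSD4, 8.267 for RIMS4, -6.056 for SYNPO, 6.381 for EBF2 and -6.804 for IL1R1, and 308 genes passed it. SYNPO was higher in KO at days 6, 8 and 9 and lower at day 16, and EBF2, high in WT day 8 and low in WT day 9, was at 234.5 CPM in KO day 16. A difference between 2 groups of days drew attention to these genes, and day 16 had 1 library a side, whose peculiarities the test cannot separate. With GC offsets 387 genes passed, 293 of them shared with the 308, and no biological explanation was tested. Simulated data gave 10 false calls among 57 in this comparison.

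PAX8, PAX2, WT1 and LHX1 headed nephron-lineage lists that were lower in KO, while POSTN and COL3A1 headed a stromal list that was higher. These list calls held at the preset correlation, and none passed with an estimated correlation. With offsets against GC content PAX8, PAX2, WT1 and LHX1 were at log2 -10.25, -3.89, -4.54 and -4.25 and still passed, which argues against the GC trend as the whole cause of their fall, and 4 of 5 lists kept their sign and at least 80% of their median, while the podocyte median went from -1.57 to -1.21 and a part played by GC content stays open there. Loss of nephron cells with every other cell type raised alike stayed open: the largest gap between the stromal mean (1.13 ± 1.07, SD over 4 days) and that of another list of at least 5 tested members, less both SDs, was -0.837, against muscle. That bound was set after seeing values, and with all list members the gap was 0.106 (endoderm) and with tested members of every list 0.0576 (endothelium, 3 genes), both of which would argue against this explanation. The means of the endothelial and endoderm lists were below 0 (-0.638 ± 0.638 and -1.22 ± 2.14), each with 3 genes tested and a positive median on 1 day. Those of the neural, muscle and chondrogenic lists were above 0 (0.174 ± 2.17, 0.0983 ± 0.796 and 0.403 ± 0.767). With these SDs the signs do not settle whether every other cell type was raised. A developmental effect of DOT1L loss on PAX8 and its partners stays open, and was not tested.

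CAT, CBR1, CTSF, MEG3 and HOXD13 belonged to 36 genes near the floor in one genotype and expressed in the other, 20 higher in KO and 16, among them PAX8, SALL3 and DACH2, higher in WT. A gain or loss of a whole autosome was argued against: the largest autosome median was 0.293 in size (chromosome 16; 0.332 with the bootstrap bounds of all autosomes), under the 0.585 of 1 copy gained, and the smallest difference of these genes was 3.16 on the log2 scale. Reads divided between near-identical genes were argued against as the cause of the whole set, since 27 of the 36, CAT and PAX8 among them, had whole counts in all 8 libraries. Genes matched on level were also mostly whole, 37.4% being non-whole in the same libraries. A read given wholly to the wrong gene would also leave a whole count, so that form of ambiguity stays open. Divided reads stay open for the 25% with a non-whole count in the genotype expressing them (22.2% to 52.8% among genes matched on level). A line difference that predates differentiation stays open: 85% of the genes near the floor in WT, 17 of 20, were at 3 counts or fewer in WT day 0, but these genes were chosen for low WT levels, 9 of the 16 higher in WT were as low there, and the series holds no KO day 0 library. Activation of genes such as CAT by DOT1L loss may give the same values.

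PAX8 and the other genes called were also set against other splits of the 8 libraries. Of the 8 splits that part all 4 days, 1, the real one, called 222 genes and the highest other called 0, and 2 called as many as the 11 lists of the real split, the highest other calling 14. A total of 8 splits is too few for a share under 0.05. Every other split also has both genotypes on each side, so the genotype difference enters its spread and lowers its gene count. The 0 therefore does not measure chance.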

How the results depend on the processing

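The alternatives on centring, whole counts, thinned libraries, ribosomal-like genes and GC offsets were chosen after seeing the data. The 20 named rises and falls were chosen for the same sign on all 4 days, so the alternatives could hardly reverse them. For PAX8, WT1, DOT1L and the other named genes, a change of sign was counted as a reversal only where either fit passed the threshold. None of 1865 comparisons with an alternative gave one: 1641 kept their side of the threshold, 123 lost it and 101 passed newly. Of 182 such comparisons of lists, 152 kept their side, 25 lost it, 5 passed newly and 0 reversed a called list. Changes of direction in uncalled lists were not counted: with GC offsets the ureteric, muscle and BMP and TGF-beta lists went from lower to higher by camera. The 222 KO genes became 1189 with no filter, 774 by DESeq2, 99 with no day term, 128 with GC offsets and 46 (without day 8) to 695 (without day 16) with a day left out (63 and 50 without days 6 and 9). Of the 20 named rises and falls, such as SALL3 and CAT, 17 passed with no day term and with GC offsets, 9 to 19 with a day left out, and 15 of the 15 in the fit of whole-count genes. For day 9 against 6, where LEFTY2 was the 1 gene called, the count was 177 with no filter, 65 by DESeq2, 2 by voom and 0 (without day 8) to 34 (without day 16). For day 16 against 9, at 0, it was 1024 with no filter, 518 by DESeq2, 9 at 1 CPM in 4 libraries, 1 by voom and 2 on log2 TPM, and 0 with day 6 or 8 left out. The interaction, 308 genes, gave 1243 with no filter, 501 by DESeq2, 0 on log2 TPM and 238 (without day 6) to 1627 (without day 9), with 668 without day 8. The 11 lists, HOX and renal vesicle among them, became 0 with an estimated correlation and 4 by fry, which asks another question, and 8 to 13 with a day left out. WT days 6 and 8 differed in 224 genes, or 358 in deposited TPM. A fit without a day has fewer samples, and otherwise the cause was not tested. The closest WT day of each KO library was the same under 4 alternatives. Days pair the libraries in the KO comparison, and the 99 genes with no day term are its unpaired version. Depth limits genes such as NPHS2 on days before they are expressed.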

Other observations

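The test of limb and lateral plate genes was chosen after TBX4 and HOXD13 were seen among the genes higher in KO, the test of thinned libraries after the depths were seen, and the genes named here after their values.

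At the imprinted locus of DLK1 and MEG3, MEG3 rose in KO and DLK1 did not pass (log2 -3.05, adjusted p = 0.0555, and 0.108 with GC offsets). DLK1 was at 1033, 1397, 147.6 and 45 CPM in WT days 6, 8, 9 and 16 and at 29.5, 168.9, 15.5 and 29.9 in KO, where MEG3, near the floor in WT, reached 1034 CPM at day 16. IGF2 was at 5092, 7996, 5984 and 6014 CPM in WT and at 1148, 5382, 1659 and 3530 in KO.

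SIX1, SIX2, NCAM1 and SOX9 were higher in KO than in WT at day 16, unlike the progenitor genes PAX2 (3.65 CPM in KO and 342.6 in WT), WT1 (8.53 and 847.3) and SALL1 (28.6 and 99.7). SIX1 was at 63.7 CPM in WT day 6 and 21.6 in WT day 16, and at 4.09 and 96.8 in KO on the same days and 84.2 in KO day 19, where SIX2 was at 89.9. NCAM1 was at 424.5 and 850.1 CPM in KO days 16 and 19 and 126.6 in WT day 16, and SOX9 at 145 and 126.8 against 25.4. The immediate early genes FOS and EGR1 were at 446.5 and 567.8 CPM in WT day 16, 23.2 and 75.5 in KO day 16 and 209.1 and 496.2 in KO day 19.

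TBX4 and HOXD13 raised the hypothesis that KO cells may have shifted towards another mesoderm. The median of further lateral plate and limb bud genes, 19 of 25 of them tested, was log2 -0.14, at percentile 22.54 of random lists matched on expression, and none rose. The outcome set before the test for no shift, a median at or below the middle of the random lists, was met. The median still lies within the range of the random lists, and the list left out genes already seen as called, so this shift stays open. TWIST1, HOXA13 and GATA4 were at 1.82, 2.60 and -3.06 without passing. HOXA13, GATA4, MSX2 and MEIS2 also belong to the fixed lists, whose values had been seen. For a shift towards paraxial mesoderm the median was -1.13 at percentile 0, with 8 of 22 genes tested. PAX3 and FOXC2 were at -2.56 and -2.78 and TBX18 at 1.54, none of them passing. These values argue against a rise of the tested genes as a set. Of them PAX3, FOXC2, TBX18, MEOX1, DLL3 and LFNG also belong to the fixed lists, whose values had been seen, and most of the paraxial list was not tested. A shift towards paraxial mesoderm itself was therefore not decided.

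Depth and labels were also examined. With the libraries thinned to 1574027 counts, all of 5 lists kept their sign and at least 80% of their median over the genes tested in both, the medians being -2.01, -1.56, -1.24, -1.56 and 0.838 for intermediate mesoderm, nephron progenitor, renal vesicle, podocyte and stroma against -2.01, -1.58, -1.19, -1.57 and 0.827 (10, 14, 10, 8 and 13 genes), and 193 genes passed against 222. By DOT1L level no library crossed between the genotypes, the highest KO library being at 111.5 CPM and the lowest WT library at 180.5.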
